A study of Homo sapiens with 8 samples.

How the data were processed

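RNA and antibody tags were measured in single cells of a pair of human colon cancer lines, SW480 and SW620. SW480 was established from a primary colon adenocarcinoma and SW620 from a lymph node metastasis of the same donor. Cells were detached with an enzyme-free buffer and stained with a library of DNA-barcoded antibodies against glycans, the sugar chains of the cell surface. RNA and antibody tags were captured together with a 10x Genomics 5′ kit and its feature barcode kit, per the labels' protocols. This kind of assay is known as CITE-seq. There were 4 stained samples. SW480 cells were stained at 5 times the antibodies' dissociation constant (KD), at 1 times KD, and at 5 times KD with 5 commercial antibodies added. SW620 cells were stained at 5 times KD. Each stained sample has an RNA part and an antibody part, so the series lists 8 samples.

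The deposited matrices hold counts of unique molecular identifiers (UMIs) per feature and cell barcode, made with Cell Ranger 7.1.0 per the file headers. The submitters' processing notes name the genome build hg38, and the gene annotation is not given in the sources used here. The deposited counts were not normalized: values were whole numbers and totals differed between matrices. The matrices hold called barcodes, and how these were called is not given in the sources used here. Each matrix lists 36601 genes and 53 antibody tags. Of the tags, 48 belong to 35 anti-glycan antibody clones and 5 to the commercial antibodies. There are 3 clones with 3 tags and 7 with 2, and a clone's value was the mean over its tags, a choice made after the tag names were seen. There were 8 matrices for the 4 stained samples. The repeats held 99.6% to 100% of the barcodes of the first-dated matrix of the same sample and further barcodes of their own, up to 12011 against 10504. Between first-dated matrices of different samples 1.08% to 1.49% of barcodes were shared, so the repeats were read as further sequencing of the same cells and counted as 1 replicate. The first-dated matrices were used, because only that date covers all 4 samples.

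These steps shape the measurements. Reads were counted near the 5′ ends of transcripts. UMI counting removes PCR copies. Whether reads on the opposite strand were counted is not given in the sources used here, so antisense transcripts such as SMARCA5-AS1 are uncertain. Genes with near-identical copies, such as MT1G, CST1, LGALS7B, the histone genes and ribosomal protein genes, may have lost or exchanged reads during mapping. Antibody UMIs per cell also depend on how deeply each antibody library was sequenced. Shares of a fixed total have another limit: when the most abundant antibody falls, the shares of the others rise.

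Barcodes with at least 500 genes detected and at most 20% mitochondrial UMIs were kept. No doublet caller was run, because each library holds 1 line and most doublets would join like cells. The alternative without cells above 2 times their library's median UMI count stands in for one. Gene UMIs were summed over kept cells and scaled by the library total to CPM. A gene was compared when it reached 10 CPM in either library, and it passed the size rule when log2(CPM + 1) differed by at least 1. Log2 differences are therefore on the log2(CPM + 1) scale, which understates the change of genes at low levels. An antibody was compared when its mean reached 1 UMI per cell in either library, and it passed when its share of all anti-glycan UMIs differed at least 1.5-fold. Intervals are exact Poisson or exact Clopper-Pearson 95% intervals and cover counting error only, and a count of 0 was given a floor of 3 counts. Every group held 1 library, so the main comparisons use size rules in place of a test, no difference has a replicate check, and no p-value is given.

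Before the data were examined, 29 gene lists were fixed. They covered glycan synthesis, mucins and other surface proteins, adhesion, cell types of the gut, the cell cycle, WNT signalling, stress, metabolism, antigen presentation, ribosomes and mitochondria, and cells foreign to these cultures. For each list with at least 5 members compared, the median log2 difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when its percentile was under 2.5 or over 97.5, which describes these libraries and is no test. The fixed rule for named genes took the 12 with the largest differences in each direction among genes with at least 50 CPM in the higher library and the same direction against all 3 SW480 libraries. It also took the 3 list members with the largest differences, the enzymes tied to named antibodies, the 6 largest antibody ratios in each direction and all commercial antibodies. For clusters it took the 5 genes with the largest fold over other cells, and for antibody and gene pairs the 10 with the largest correlations. XIST and Y-linked genes were left out. Of the list members that the rule names, 1 is not reported here. No reference genome was used, so no coordinates are given, and gene symbols are those of the files.

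SW480 cells of the 3 libraries were clustered together, and SW620 cells separately, from RNA alone (scanpy 1.11.5; 2000 variable genes, 30 principal components, 15 neighbours, leidenalg 0.10.2 at resolution 0.5, seed 0). The antibodies thus had no part in defining clusters. An antibody differed in a cluster when its mean was at least 1 UMI per cell and its share differed at least 1.5-fold in the same direction in all 3 libraries, in a cluster with at least 100 cells in each. Relations across cells were rank-based partial correlations between an antibody's share and a gene's CPM, given total RNA and antibody UMIs. They used genes with a UMI in at least 20% of cells of each SW480 library and passed at a size of at least 0.1 with the same sign in all 3. Cells are not replicates, so these are descriptions.

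The RNA size rule was also run on simulated counts, with expression levels and variation taken from the real libraries. With 9002 genes, all genes changed 2.5-fold, 4-fold or 0.25-fold passed the RNA size rule (100% each), and 0% of those changed 1.5-fold and of unchanged genes did. The simulated variation was that among the 3 SW480 libraries, so the simulation does not cover how SW620 libraries would vary. The antibody, cluster and gene list rules were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used. As an alternative, edgeR 4.0.16 fitted the 3 SW480 libraries against the lone SW620 library, which was assumed to vary like the SW480 libraries. Other alternatives changed the scaling, the minimum, the pseudocount, the cells kept, the library compared, the dated matrix, the clustering resolution, the fold threshold and the covariates. Alternatives without the HuA tags in the antibody total, with median-centred antibody ratios for clusters, without clusters of low RNA content, and with each tag counted separately were added after the data were seen.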

Results

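The data joined the RNA of single colon cancer cells with the binding of 35 anti-glycan antibodies to the same cells. There were 4 stained samples of 1 library each: SW480 at 5 times KD, SW480 at 1 times KD, SW480 at 5 times KD with 5 commercial antibodies, and SW620 at 5 times KD. After filtering they held 10594, 8532, 10255 and 8718 cells, which was 95.6%, 97.6%, 97.6% and 97.3% of their barcodes. Over all deposited barcodes, gene UMIs totalled 158215203, 137194464, 126636506 and 129862142 in the same order. Antibody UMIs, those of commercial antibodies included, totalled 38860863, 32441676, 36956991 and 29080291. The median kept cell held 13075.5, 13998.5, 10050 and 13551 gene UMIs. SW620 cells had a median mitochondrial share of 3.65%, against 2.54% to 2.80% in the SW480 libraries. Across genes, log2 CPM of the SW480 5x library correlated with the 1x library at 0.998 and with the commercial library at 0.999 (Pearson). Its correlation with SW620 was 0.826. Genes are not independent replicates.

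The first comparison asked how the metastasis-derived line differs from the line of the primary tumour in RNA. Several transcripts abundant in SW480 cells, such as LCN2, KRT13 and TGM2, were almost missing from SW620 cells. LCN2, which encodes the secreted siderophore-binding protein lipocalin-2, stood at 1287 CPM in SW480 (95% interval 1282 to 1293) and 0.728 CPM in SW620 (0.588 to 0.891), a log2 difference of −9.54. In the other direction, SW620 expressed neuroendocrine granule genes such as CHGB and SCG2, the muscle-type tropomyosin TPM2, and MFNG, a glycosyltransferase that extends O-fucose on Notch receptors. At 2-fold or more, 725 of 9569 genes were higher in SW620 and 741 were lower.

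Among the genes lower in SW620, the keratins KRT13 (626 CPM in SW480, 0.0387 in SW620) and KRT5 (361 and 1.87) differed by −9.24 and −6.98. The protein-crosslinking enzyme TGM2 went from 382.5 to 1.84 CPM (−7.08) and MIA from 162 to 0.101 (−7.21). The G protein subunit gene GNG11 had 133 CPM in SW480 and 0 UMIs in SW620, at least 5706-fold lower. PHLDB2 (137 and 0.0774 CPM), the cysteine protease inhibitor gene CST1 (140 and 0.155) and IGFBP7 (119 and 0.0852) differed by −7.00, −6.93 and −6.79. ANKRD1, a target of the transcription regulator YAP, stood at 128 and 0.263 CPM (−6.68). The uncharacterised transcripts AC016074.2 (ENSG00000286122, 184 and 0.434 CPM) and AC104823.1 (ENSG00000224099, 82.2 and 0.0619 CPM) completed the set, at −7.01 and −6.29.

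Among the genes higher in SW620, SHISA9 rose from 0.362 to 84.3 CPM (5.97), MFNG from 0.546 to 82.7 (5.76), TPM2 from 4.86 to 265 (5.51) and TOX3 from 3.33 to 117 (4.77). The metallothionein MT1G (1.16 and 54.1 CPM), LINC00460 (2.11 and 77.4), IGFBP1 (1.88 and 65.4) and NUPR1 (1.54 and 50.2) differed by 4.67, 4.66, 4.53 and 4.33. CHGB, which encodes the secretory granule protein chromogranin B, stood at 3.85 and 88.5 CPM (4.21), and PLLP at 3.32 and 71.0 (4.06). AC073968.2 (ENSG00000286738) and CYTL1 each had 1 UMI in SW480, against 120 and 56.2 CPM in SW620. Their log2 CPM ratios had counting intervals of 11.73 to 19.51 and 10.63 to 18.42.

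Of the 29 fixed gene lists, 23 had enough members to be ranked and 8 stood apart from random lists. If genes varied independently of each other, 1.15 would. Random lists were drawn gene by gene, while genes of a fixed list may vary together and some lists share members such as CD44. The 1.15 is therefore no measure of chance for these lists. The enteroendocrine list lay highest, with 4 of 5 measured members higher and 1 lower (median log2 difference 3.26, percentile 100). SCG2 (5.44), CHGB (4.21), CHGA (3.26) and SYP (1.83), which encode proteins of secretory granules and vesicles, were higher and PCSK1N was lower (−2.14). Of 38 S phase genes, 6 were higher and 0 lower (median 0.57, percentile 100), among them CDCA7 (1.60), HELLS (1.49) and the replication clamp PCNA (1.09). All 13 mitochondrially encoded genes were measured and 1 passed, MT-ND6 (1.03); the list's median was 0.50 (percentile 99.95), with MT-CO3 at 0.95. These values stood beside the higher median mitochondrial share of SW620 cells (3.65% against 2.72%).

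The invasion and protease list fell furthest, with 9 of 15 measured members lower in SW620 and 0 higher (median −1.23, percentile 0). Beside LCN2 it held the metalloprotease inhibitor TIMP3 (−3.74), the urokinase receptor PLAUR (−2.73) and the lysosomal protease CTSL (−1.99). Of 23 genes for epithelial junctions and keratins, 4 were lower and 1 higher (median −0.42, percentile 0.01). P-cadherin (CDH3, −3.67), CLDN7 (−2.49) and JUP (−1.19) were among the lower ones, and the keratin KRT7 was higher (2.09). Of 20 genes for glycosaminoglycans and proteoglycans, 3 were lower and 1 higher (median −0.35, percentile 0.25). The heparan sulfate proteoglycans SDC4 (−2.24) and GPC1 (−1.10) and the epimerase GLCE (−1.23) were lower, and CSGALNACT2 was higher (1.02). Of 54 genes for G2 and M phase, 2 were lower, CDC25C (−1.33) and CDCA3 (−1.04), and CBX5 was higher (1.04), with a median of −0.14 (percentile 0.16).

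The WNT target and stem cell list was split, with 8 of 19 measured members lower and 3 higher (median −0.36, percentile 0.865). CD44 (−3.87), APCDD1 (−3.13), AXIN2 (−1.68) and CCND1 (−1.23) were lower, and the crypt stem cell genes LGR5 (2.40) and SMOC2 (2.04), with NKD1 (1.28), were higher. The WNT inhibitor gene DKK4 had 2 UMIs in SW620, and its log2 CPM ratio had a counting interval of −14.19 to −9.29. This list kept its place in 3 of 5 other settings, with percentiles up to 26.9. The G2 and M phase list kept its place in 4 of 5, with percentiles up to 2.79. The glycosaminoglycan and enteroendocrine lists also kept theirs in 4 of 5. Wherever these 2 lists had a percentile it stayed beyond the cut, at 0.21 to 1.71 and at 100.

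Apart from the glycosaminoglycan and proteoglycan list, the lists for glycan synthesis lay within the range of random lists, although single enzymes differed. Of 8 fucosylation genes measured, 1 was higher (median 0.19, percentile 63.0). This was GMDS, an enzyme gene of the pathway to the fucose donor GDP-fucose (85.0 CPM in SW480 and 197 in SW620). FUT4 stood at 0.87 and FUT1 at −0.64. Of 11 sialylation genes, ST3GAL2 was higher (1.72) and ST6GALNAC3 (−2.35) and ST6GALNAC6 (−1.64) were lower (median 0.21, percentile 69.1). Of 9 genes for mucin-type O-glycans, GALNT7 was higher (1.13) and GALNT3 lower (−2.50), with a median of 0.23 (percentile 69.1). Of 5 glycosphingolipid genes, UGCG, which makes glucosylceramide, was lower (53.8 CPM in SW480 and 12.7 in SW620), as was ST6GALNAC6 (median 0.12, percentile 55.1). None of the 9 N-glycan genes (median −0.19, percentile 4.39; MGAT5 −0.77) and none of the 10 genes for LacNAc chains (median 0.22, percentile 67.9; B3GNT2 38.1 CPM in SW480 and 18.6 in SW620) passed. Mucins and other glycosylated surface proteins had 4 of 17 members lower and 1 higher (median −0.18, percentile 4.91). The growth factor receptor gene EGFR (−5.75), CD44, the integrin chain ITGA3 (−3.08) and CD9 (−1.34) were lower and CD24 was higher (1.03). None of 5 galectin genes passed (percentile 40.9; LGALS3BP 0.77), and their median was −0.04, or 0.01 with TMM scaling.

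Other programmes also lay within the random range. Of 9 mesenchymal genes 3 were higher, led by the transcription factor gene ZEB1 (1.58), and 3 were lower, CDH11 (−3.34), FN1 (−2.57) and AXL (−1.82), with a median of −0.38 (percentile 7.09, but 97.9 in 1 of 5 other settings). For antigen presentation, PSMB10 was higher (1.67) and HLA-E (−1.65) and PSMB9 (−1.12) were lower among 15 genes (median −0.12, percentile 11.7). Among 9 interferon genes IFITM1 (−3.99) and IFI35 (−1.07) were lower (median −0.43, percentile 3.89). Of 22 hypoxia and glycolysis genes 5 were higher, led by the carbonic anhydrase gene CA9 (3.96), and 4 were lower, led by the glucose transporter gene SLC2A3 (−3.67) and ALDOA (−1.93), with a median of 0.20 (percentile 81.6). Cholesterol synthesis had 3 of 18 genes lower, led by STARD4 (−2.26), and 0 higher (median −0.17, percentile 8.16). Stress genes had 4 of 21 lower, FOS (−1.97), ASNS (−1.93), EGR1 (−1.73) and HSPH1 (−1.27), and 0 higher (median −0.17, percentile 3.57). None of the 89 genes of the ribosomal list passed (percentile 16.5), with a median of −0.02, or 0.03 with TMM scaling; RPL7A stood at −0.85. The kinase genes RPS6KA2 (−0.95) and RPS6KA5 (−0.85), which make no ribosomal protein, entered this list through their symbols. Of 4 enterocyte genes TSPAN1 was lower (−1.13) and HNF4A higher (1.04), and of 2 goblet cell genes TFF3 was higher (3.24), with too few measured to rank either list. No marker of T and B cells, myeloid cells, fibroblasts and endothelium, or red cells reached 10 CPM. The highest were CD4 (3.20 CPM in SW620), CD68 (2.24 CPM in SW620), ACTA2 (3.08 CPM in SW480) and HBA1 (0.750 CPM in SW480).

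**Figure D1:**
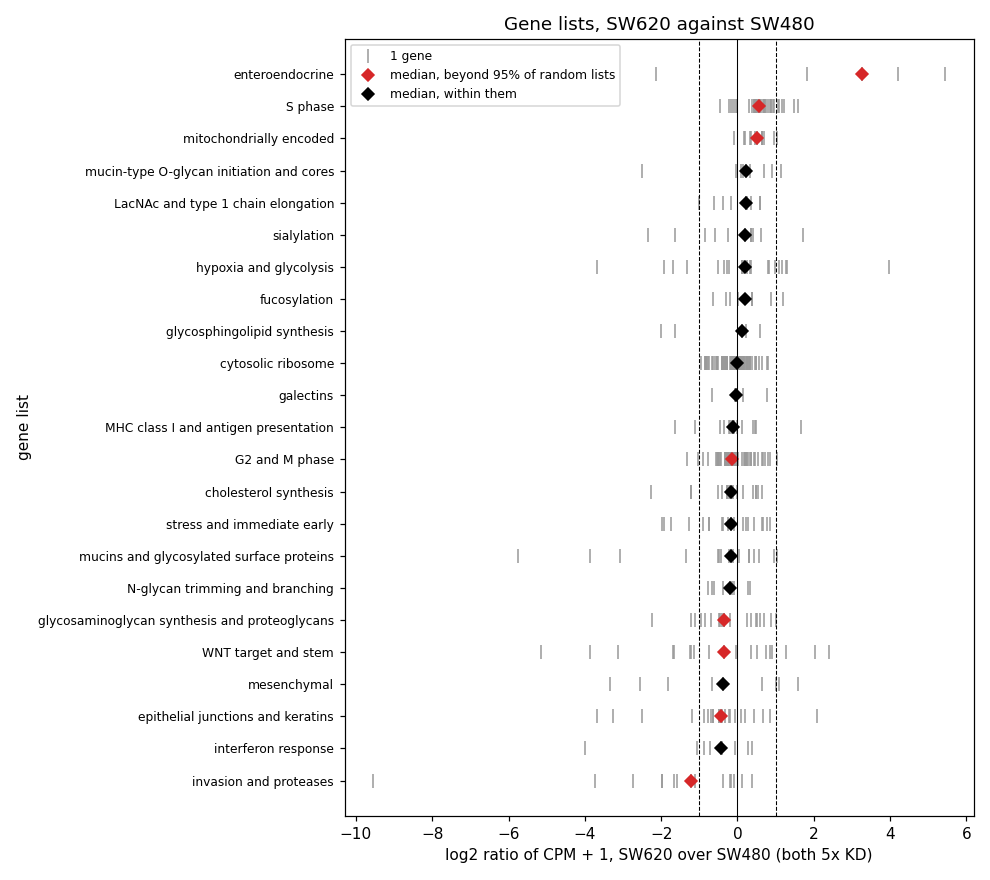
Median log2 difference, SW620 minus SW480 at 5 times KD, on the log2(CPM + 1) scale, for each ranked gene list, with its members as points. The enteroendocrine list lies highest (median 3.26) and the invasion and protease list lowest (−1.23).

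With n = 1 library per line these are differences between libraries with no replicate check. By the same rule 0 genes differed between the SW480 5x library and either other SW480 library, and 631 genes were higher and 700 lower in SW620 against each of the 3, which share the 1 SW620 library. The median of all genes was 0.11 with CPM and 0.16 with TMM scaling, and genes higher in SW620 made up 49.5% and 53.9% of those passing.

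Next, antibody binding was compared between the lines at 5 times KD. SW620 cells carried a larger share of the antibodies Panko2, FG129, 1116NS19.9, Mu3S193 and H18A. The share of Panko2 rose 4.91-fold, from 0.112% to 0.551% of anti-glycan UMIs per tag, and its mean UMIs per cell 4.52-fold, from 3.94 to 17.8. In the median cell Panko2 went from 2 to 4.5 UMIs. The highest 10% of cells held 46.7% of its UMIs in SW480 and 62.0% in SW620. FG129, raised against sialyl-di-Lewis a, rose 2.83-fold by share and 2.61-fold per cell (2.61 to 6.79 UMIs). The antibody 1116NS19.9, which binds sialyl Lewis a (the CA19-9 antigen), rose 2.16-fold by share and 1.98-fold per cell (16.5 to 32.7 UMIs). In the median cell 1116NS19.9 went from 6 to 10 UMIs. The other sialyl Lewis a antibody, 5B1, did not pass, at 1.32-fold by share and 1.21-fold per cell (1.31 to 1.58 UMIs). With HuA left out of the total, 5B1 stood at 0.879-fold and 1116NS19.9 at 1.44-fold. Mu3S193, which binds Lewis Y, rose 1.84-fold by share and 1.69-fold per cell (165 to 279 UMIs), and H18A 1.75-fold by share. The most abundant antibody, HuA, fell from 58.4% to 37.7% of antibody UMIs, from 684 to 407 UMIs per cell per tag.

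By the 1.5-fold rule 5 of 29 antibodies compared were higher in SW620, 5 were lower and 6 more lay below the minimum. By share the lower ones were FB5.7 (0.285-fold; 0.262-fold per cell, from 1.14 to 0.298 UMIs), BMS-986012 against fucosyl-GM1 (0.628), B72.3 against sialyl Tn (0.634), 132-3 (0.638) and HuA (0.646). In the median cell 132-3 went only from 6 to 5 UMIs, BMS-986012 from 43 to 25 and HuA from 127 to 76.7. FB5.7 and B72.3 each went from 1 to 0 UMIs there. Next below the threshold came the Lewis X antibody 291-2G3-A (1.46), and the next lower ratio was 0.764. The 10 clones with several tags gave like ratios for their tags, with a median log2 range of 0.053 and a largest of 0.32 (MC651). The chlamydial lipopolysaccharide antibody S25-23, whose target is foreign to human cells, stood at 0.805 and 0.863 UMIs per cell, and the HIV envelope glycan antibody PGT121 at a ratio of 0.913.

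The counts depended on what the shares were measured against. The median antibody shifted by −0.17 (log2), and relative to that shift 8 antibodies were higher and 1 lower. Without HuA in the total, 2 were higher, Panko2 (3.29-fold) and FG129 (1.89-fold), and 17 were lower. Panko2 and FG129 higher and FB5.7 lower held under every scaling tried, all of which use the same counts. FB5.7 lay near the level of S25-23 (1.14 and 0.298 UMIs per cell against 0.805 and 0.863), so its fall is uncertain as a glycan difference. B72.3 was low too, at 1.62 UMIs per cell in SW480 and 0.943 in SW620, so its fall is likewise uncertain.

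**Figure D2:**
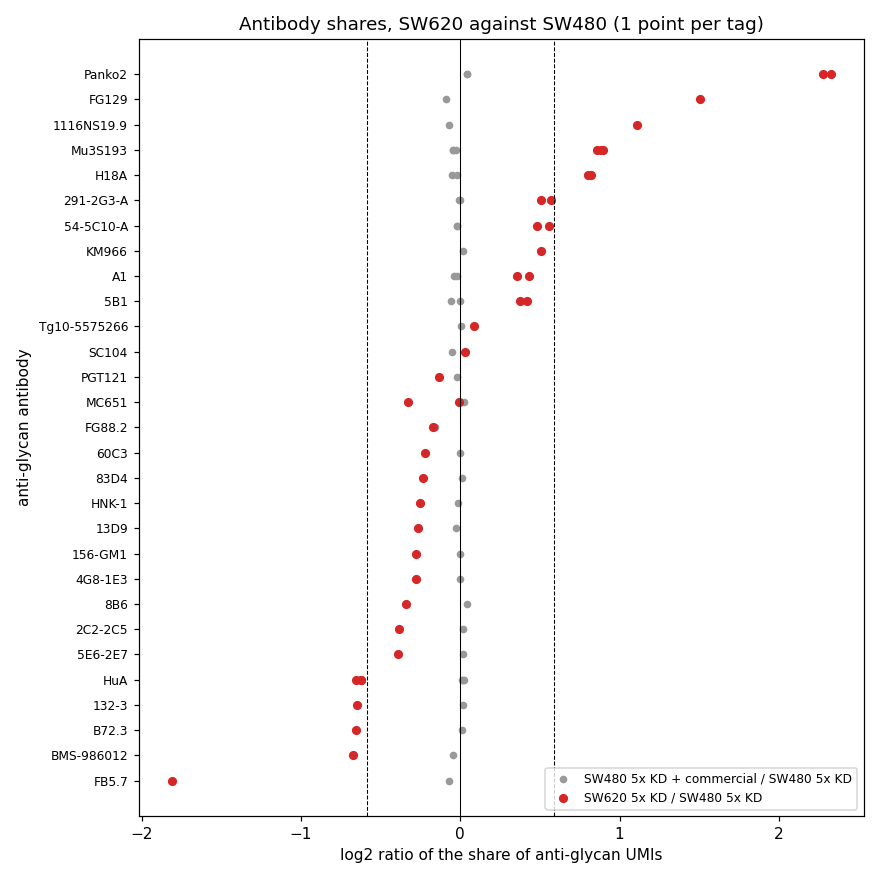
Log2 ratio of antibody shares for SW620 over SW480 at 5 times KD and for SW480 with over without commercial antibodies, 1 point per tag. As means over tags, SW620 over SW480 spans 0.285-fold (FB5.7) to 4.91-fold (Panko2), while the ratios with and without commercial antibodies stay between 0.897 and 1.03.

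The enzymes tied to these antibodies were mostly at low levels in both lines. For Lewis Y and Lewis X, FUT1 stood at 10.3 CPM in SW480 and 6.26 in SW620, and FUT4 at 11.2 and 21.2. For sialyl Lewis a, FUT3 had 5 and 8 UMIs in all kept cells, B3GALT5 629 and 454 UMIs, and ST3GAL3 13.4 and 17.5 CPM. FUT6 had 6 and 0 UMIs and FUT9 6 and 2. For sialyl Tn, ST6GALNAC1 had 1 UMI in each line. C1GALT1 (47.7 and 52.5 CPM) and its chaperone C1GALT1C1 (24.5 and 28.9) act on Tn, and B4GALNT1 (1.02 and 1.90 CPM) and ST8SIA1 (30 and 14 UMIs) make gangliosides. At these counts a difference in FUT3 or ST6GALNAC1 was not detectable.

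The comparison of 5 with 1 times KD asked how staining concentration changed the readout in SW480 cells. Most antibodies held their share of the total: of 29 compared, 0 were higher at 5 times KD by 1.5-fold and 1 was lower. That antibody was 291-2G3-A, with a share of 2.08% per tag at 5 times KD and 3.65% at 1 times KD (0.570-fold). It had 73.0 and 133 UMIs per cell (0.548-fold). Panko2 came next (0.697). The largest ratios belonged to SC104 (1.42), PGT121 (1.29) and BMS-986012 (1.24). Ratios above 1 were found for 23 antibodies, with a median of 1.09. The mean antibody total per cell was 3514 UMIs at 5 times KD and 3653 at 1 times KD, a total that sequencing depth also sets. In RNA, 0 of 8888 genes passed, and the largest difference was SNHG19 (0.50).

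Adding 5 commercial antibodies left the anti-glycan antibodies nearly as they were. The ratios of their shares to the SW480 5x library ran from 0.897 to 1.03, so 0 of 29 passed, and 0 of 8992 genes passed in RNA (largest, SMARCA5-AS1 at 0.90). Of the commercial antibodies, those against CD44 gave the most UMIs, IM7 with 13.4 UMIs per cell (13.3 to 13.5) and BJ18 with 10.0 (9.98 to 10.1). The CD15 antibody W6D3 had 0.705 (0.689 to 0.721), and the CD133 antibodies S16016B and clone7 had 0.110 (0.104 to 0.117) and 0.0582 (0.0536 to 0.0631). Each had 0 UMIs in the other libraries, which allows up to 0.271, 0.343 and 0.335 UMIs per 1000 barcodes in SW480 at 5 and 1 times KD and in SW620. Across cells BJ18 and IM7 correlated with each other at 0.842 and with CD44 mRNA at 0.385 and 0.378. W6D3 correlated with the Lewis X antibody 291-2G3-A at 0.320. PROM1, the CD133 gene, had a UMI in 0.0488% of cells, and the CD133 antibodies correlated with it at −0.006.

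Within SW480, RNA clusters were compared to see whether glycan binding follows transcriptional state. The 3 libraries shared 9 clusters, of which 7 had enough cells in each. Cluster 1, with 28.3%, 24.96% and 27.9% of cells, was led by the Paneth cell defensin DEFA5 (17.5-fold over other cells) with DKK4, MYH7B, LINC01170 and CCSER1. It bound less HuA, and by share 25 antibodies were higher there. HuA stood at 0.306, 0.221 and 0.282 times the share of the other cells (5x, 1x and commercial libraries), 291-2G3-A at 4.50, 4.99 and 4.72 times, FG88.2 at 5.78, 6.41 and 4.60 times, and SC104 at 7.30, 8.10 and 7.64 times. In UMIs per cell, which need no total, HuA stood at 0.151, 0.131 and 0.133 and 291-2G3-A at 2.22, 2.95 and 2.23.

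Cluster 2 (22.3%, 23.9% and 23.2% of cells), led by CXCL14, PSG5, GNG11, NANOS1 and PIP5K1B, had more Panko2 by share (2.01, 1.999 and 2.09) and less SC104 (0.187, 0.147 and 0.144). Clusters 3 and 5 were G2 and M phase-like but differed in glycan binding. Cluster 3 (16.9%, 18.1% and 17.2%), led by AURKB, DHRS2, UBE2C, RRM2 and HIST1H2BJ, had low shares of 291-2G3-A (0.258, 0.304 and 0.269) and SC104 (0.126, 0.197 and 0.137), beside 3.45, 1.95 and 3.78 times the HuA UMIs per cell. Cluster 5 (6.30%, 6.24% and 6.69%), led by PSRC1, NEK2, KIF20A, APOLD1 and OIP5, had high 291-2G3-A (3.77, 3.49 and 3.65) and low HuA (0.259, 0.203 and 0.239). Cluster 4 (12.7%, 17.9% and 13.4%), led by AC019349.1, KRT13, TNFRSF6B, MIA and S100A2, had little SC104 (0.148, 0.167 and 0.107). Cluster 6, led by PTGDS, SPNS3, SLPI, S100P and GGH, had no antibody past 1.5-fold by share in all 3 libraries, although SC104 reached 2.27, 1.22 and 1.86, and per cell 12 antibodies were higher. Cluster 8, enteroendocrine-like with CHGA 43.4-fold over other cells, then SCG3, CHGB, CPLX2 and VGF, had low 291-2G3-A (0.338, 0.285 and 0.348) and FG88.2 (0.324, 0.335 and 0.337).

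By share, 27 of 35 antibodies differed in at least 1 cluster in all 3 libraries. With HuA left out of the total 13 did, and with median-centred ratios 10 did. In cluster 1 the rises of 291-2G3-A, 5B1, FG88.2 and SC104 and the fall of HuA held under all 4 scalings. In cluster 2 the falls of 291-2G3-A, 5B1, FG88.2, 1116NS19.9 and SC104 held, but the rise of Panko2 did not hold in UMIs per cell (1.005, 1.35 and 0.945). In cluster 3 the fall of SC104 held, but that of 291-2G3-A did not in UMIs per cell (0.596, 0.439 and 0.684). In clusters 4 and 8 the falls of 291-2G3-A, FG88.2 and SC104 held, and in cluster 5 the rise of 291-2G3-A and the fall of HuA.

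**Figure D3:**
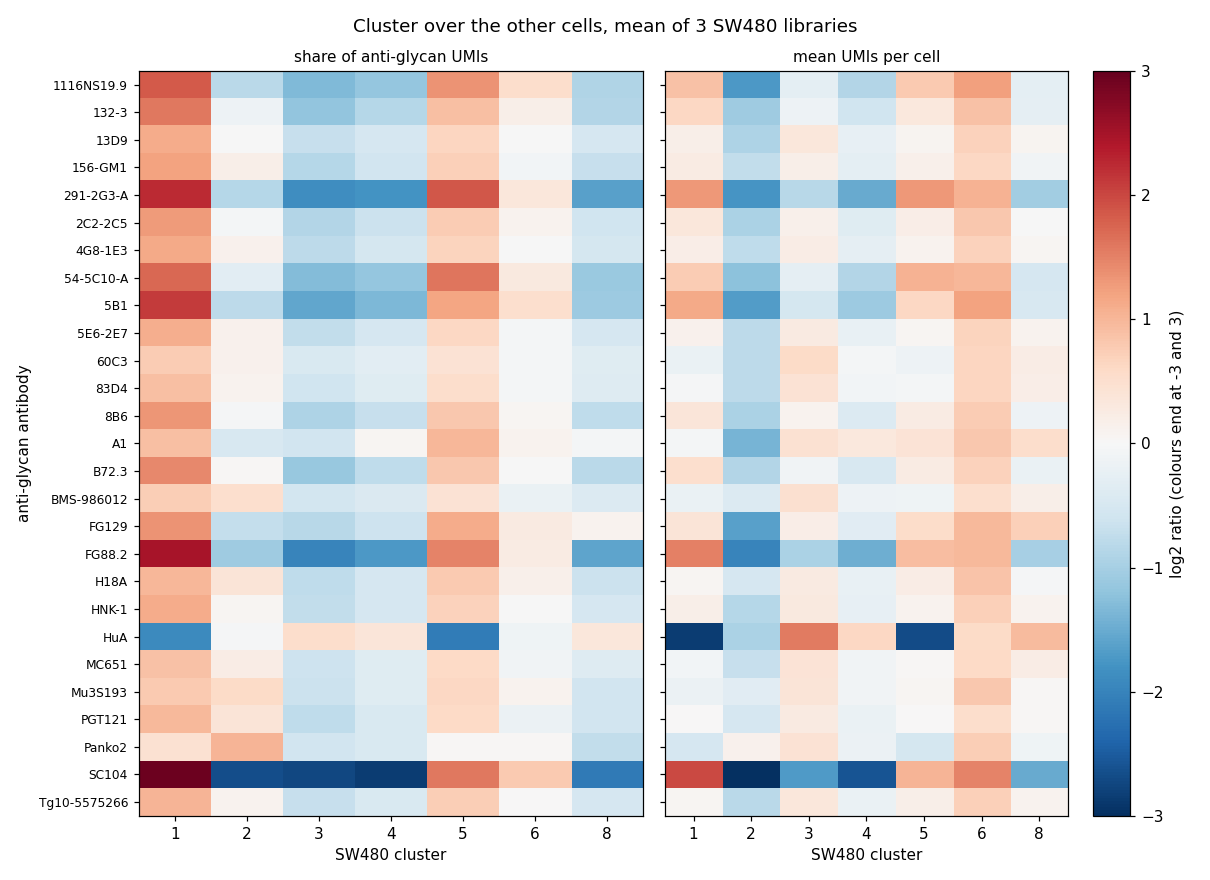
Log2 ratio of each antibody in an SW480 cluster to the other cells, as the mean over the 3 SW480 libraries. Only antibodies that differed in at least 1 cluster are drawn, by share (left) and by mean UMIs per cell (right). Colours are capped at the ends of the scale. HuA is low in clusters 1 and 5, where 291-2G3-A is high.

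Among relations between antibodies and genes across SW480 cells, 291-2G3-A took part in the most, with 2309 genes past the rule. Its share rose with ROBO2, an axon guidance receptor gene (0.617, 0.648 and 0.603 in the 5x, 1x and commercial libraries), and MYH7B (0.570, 0.621 and 0.557). It fell with ANXA2, a membrane-binding annexin gene (−0.609, −0.635 and −0.602), LCN2 (−0.571, −0.608 and −0.583) and AKAP12 (−0.569, −0.574 and −0.567). Its pairs with ZFP36L1, S100A2, ASPSCR1 and SEMA3A were also among the 10 largest, with 54-5C10-A and LCN2 (−0.553, −0.572 and −0.555). HuA, the most abundant antibody, went the other way with ROBO2 (−0.461, −0.522 and −0.435) and AKAP12 (0.460, 0.481 and 0.458). Since these are shares of 1 total, a change in HuA alone could move the share of 291-2G3-A. Of 223860 pairs, 8300 passed in all 3 libraries (3.71%), 3266 positive and 5034 negative. After cells were shuffled 0 passed. With this many cells, shuffled values lie far below 0.1, so that 0 was set in advance and weighs no cause. The genes were chosen by detection in SW480. Of the 8300 pairs, 1093 had a gene seen in too few SW620 cells, such as LCN2 (0.998%), so their SW620 values decide nothing. Of the other 7207 pairs, 419 had the same sign and size in SW620 cells, 536 the opposite sign at that size, and 6252 were smaller. Of 21 antibody and enzyme pairs fixed by glycan, 19 had an enzyme seen in too few cells for the rule, so they decide nothing. The other 2, of the Tn antibody 83D4 with C1GALT1 and C1GALT1C1, did not pass, and the largest size over all 21 was 0.0595.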

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

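The tests on barcodes left out by the cell filter were chosen after the result was seen, as were the comparison of G2 and M phase-like cells between the lines and its rerun without low-RNA clusters. Barcodes that the cell filter removed bound most antibodies more than kept cells, a signal in data the comparisons did not use. In the SW480 5x library only HuA, Mu3S193 (0.828), A1 (0.597) and SC104 (0.901) were not higher per barcode in the 485 barcodes left out. The largest rises there were those of 132-3 (10.97-fold), B72.3 (10.94-fold) and 2C2-2C5 (7.70-fold). The same antibodies were 21.8-, 18.3- and 16.3-fold higher at 1 times KD, 12.1-, 11.6- and 8.42-fold with commercial antibodies, and 10.7-, 9.94- and 5.95-fold in SW620. A candidate explanation is uptake by damaged cells without regard to the glycan. The control-like S25-23 was also higher in the barcodes left out, with a lowest ratio of 2.19 over the 4 libraries, which this explanation needs. A single common factor is excluded, because the highest antibody ratio was at least 22.1 times the lowest in each library. HuA stood at 0.395, 0.855 and 0.346 in the SW480 5x, 1x and commercial libraries, but at 1.30 in SW620. The design gives no group for a biological explanation, so none was tested, and what sets the antibodies apart stays open.

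By share, the HuA ratio of G2 and M phase-like to other cells lay on opposite sides of 1 in the lines, but per cell this rested on clusters with little RNA. In SW620 the ratio of shares was 0.565, and in the SW480 5x, 1x and commercial libraries it was 1.28, 1.11 and 1.30. Without the low-RNA clusters these were 0.856 in SW620 and 1.41, 1.11 and 1.44 in SW480. In UMIs per cell HuA stood at 0.627 in SW620 and 2.44, 1.40 and 2.61 in SW480, but without those clusters at 1.26 in SW620 and 2.90, 1.41 and 3.20 in SW480, so the opposite direction did not hold per cell. Of the 27 antibodies compared here, 16 including HuA went opposite ways by share, and of the 10 named for the line comparison, 5. Besides HuA these 5 were Mu3S193, 291-2G3-A, H18A and BMS-986012, at 1.43, 1.68, 1.53 and 1.10 in SW620 and 0.684, 0.603, 0.666 and 0.708 in the SW480 5x library, with values below 1 in the other SW480 libraries too. Without the low-RNA clusters they stood at 1.04, 1.34, 1.11 and 1.00 in SW620. All 34 antibodies other than HuA had shares below 1 in the 3 SW480 libraries. In UMIs per cell Mu3S193, H18A and BMS-986012 were above 1 in both lines (1.30, 1.27 and 1.35 in the SW480 5x library; 1.58, 1.69 and 1.22 in SW620), as was 291-2G3-A (1.15 and 1.86) except in the 1x library (0.960), so their opposite direction did not hold per cell either. The clusters that make up these cells disagreed within each line. In the SW480 5x library HuA stood at 1.49 in cluster 3 and 0.259 in cluster 5, and 291-2G3-A at 0.258 and 3.77. In SW620 HuA stood at 0.309 in cluster 2 and 1.53 in cluster 5, so the pooled values depend on how many cells each cluster holds. Cluster 5 of SW620 also had the S phase list genes CDC45 and RAD51AP1 among its leading genes. Cluster 3 of SW480 likewise had the S phase list gene RRM2 among its leading genes. The pooled cells of either line may therefore not be of G2 and M phase alone. The difference between the lines was not tested.

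Among the 10 largest antibody and gene pairs in SW480, 8 had the opposite sign in the 1 SW620 library. All were with 291-2G3-A: ROBO2 stood at −0.0622 in SW620, ANXA2 at 0.129, ZFP36L1 at 0.0690, AKAP12 at 0.183, S100A2 at 0.146, MYH7B at −0.0125, ASPSCR1 at −0.111 and SEMA3A at −0.0399. MYH7B was seen in 18.3% of SW620 cells, below the 20% asked of genes in SW480, and the others in 53.0% or more. In SW620 only ANXA2, AKAP12, S100A2 and ASPSCR1 reached the size of 0.1 that the rule asks. ROBO2, ZFP36L1, MYH7B and SEMA3A stayed below it, so by that rule they show no reversed relation. The difference between the lines in these pairs was not tested either.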

How the results depend on the processing

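The alternatives added after the data were seen were the totals without HuA, median-centred ratios for clusters, cells without low-RNA clusters, and tags counted separately. Of the summary counts, 86 under planned and 13 under added alternatives stayed within 1.5 times the main count, and 19 and 7 moved. Of single antibodies, 48 and 19 kept their side of the threshold, 7 and 3 no longer passed, and 0 reversed.

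Without a CPM minimum 1115 genes were higher and 1641 lower in SW620, and with CPM at least 50 the counts were 260 and 239, since the minimum sets how many genes are compared. The edgeR fit, which assumes that the lone SW620 library varies like the SW480 ones, gave 668 and 912. For commercial antibodies, 2 genes passed with mitochondrial and ribosomal genes out of the totals (AC024909.1, AC008622.2), 2 without a minimum (AC024909.1, MT4) and 1 without high-UMI cells (SMARCA5-AS1). For 5 against 1 times KD, 1 passed without a minimum (MT4).

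For antibodies in SW620, median-centred ratios gave 8 higher and 1 lower, the 2-fold threshold 3 (Panko2, FG129, 1116NS19.9) and 1 (FB5.7), totals without HuA 2 and 17, and separate tags 9 higher. At 5 against 1 times KD, 1 antibody was higher by mean share per cell (PGT121), 1 in second-dated matrices with the commercial library (SC104) and 1 without low-RNA clusters (SC104). With median-centred ratios 2 were lower (291-2G3-A, Panko2), at 2-fold 0, and as separate tags 2. With CPM at least 50, 4 gene lists stood apart. The mesenchymal list stood above random lists in 1 of 5 other settings (percentile 97.9), against 7.09 in the main one. The interferon list stood below them in 1 and the stress list in 2. Cluster antibodies numbered 13 without HuA and 10 when median-centred. Pairs numbered 23737 at a size of 0.05, 3790 at 0.15 and 12213 without HuA in the total. Except for the minimum, the thresholds, the totals and the separate tags, whose construction changes what is counted, the cause was not tested. No paired analysis was possible because each group holds 1 library and no main result comes from a test. FUT3, with 5 and 8 UMIs, had too few to show a difference.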

Other observations

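The tests of the other 5x library and of the single tags at 1 and 5 times KD were chosen after the result was seen, as was the gene MT4. SW620 cells, clustered alone, also had states with different antibody shares, in 1 library. Cluster 1 (29.1% of cells), led by S100A3, KRT86, LINC02241, KRT16 and QPCT, had a HuA share of 0.339 times that of other cells and 1.88 times the Mu3S193. Cluster 2 (26.4%), G2 and M phase-like, had low HuA (0.309) and Panko2 (0.292) and more 291-2G3-A (1.97) and H18A (1.998). Cluster 3 (21.5%), led by G0S2, IFITM3, the goblet cell gene TFF3, FOLR1 and ANXA1, had more SC104 (2.90), Panko2 (2.87) and 1116NS19.9 (2.06). Cluster 5 (9.84%) was named G2 and M phase-like from 3 list genes among its top 10, KIF20B, BIRC5 and AURKA. Its top 10 were led by TK1 and also held the S phase list genes CDC45 and RAD51AP1, so the name is uncertain. It had more SC104 (2.61), Panko2 (1.96) and HuA (1.53).

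Cluster 4 of SW620 (11.8%) was low in RNA and high in mitochondrial UMIs (median 11.7%), and its cells carried 5.98 times the HuA UMIs per cell of other cells. The low-RNA cluster 7 of SW480 (4468 median gene UMIs, 8.52% mitochondrial) carried 2.75, 2.27 and 3.13 times the HuA UMIs per cell in the 5x, 1x and commercial libraries. That cluster held 5.14%, 0.668% and 4.58% of cells. HuA and SC104 binding was uneven over cells: the highest 10% of cells held 68.3%, 52.7%, 72.9% and 71.4% of HuA UMIs (SW480 5x, 1x, commercial, SW620) and 94.7% to 96.3% of SC104 UMIs. In RNA, 472 of 474 MT4 UMIs in the SW480 5x library came from 1 cell.

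In SW480 cluster 1, HuA was low and 291-2G3-A high in all 3 libraries. A fixed total alone is excluded, because 291-2G3-A rose at least 2.22-fold in UMIs per cell. General uptake is argued against by S25-23, over whose change 291-2G3-A rose at least 2.69 times. A faulty tag is argued against by both tags, with a lowest ratio of 4.22. The design names no group for these cells, so no biological explanation was tested, and other technical causes stay open.

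The lower share of 291-2G3-A at 5 than at 1 times KD was weighed in the same way. Another mix of clusters as the whole cause is argued against, since within clusters 1 to 4 the ratio closest to 1 was 0.791, although it ranged from 0.526. With the commercial 5x library in its place, the ratio closest to 1 was 0.819, in cluster 2. A fault of the 5x library alone is argued against by the other 5x library (0.568), and a faulty tag by both tags (at most 0.571). Both 5x libraries were set against the same 1x library, so a fault of that library was not tested and stays open. No biological explanation was tested.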
